A study of Bacillus subtilis with 12 samples.

How the data were processed

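Transcript levels were measured on 12 two-colour arrays, each carrying the RNA of 1 sample of Bacillus subtilis labelled with Cy5 and a reference RNA labelled with Cy3, per the labels. The labels place 3 arrays in each of 4 groups, made by 2 strains and by treatment with HPUra or none. Channel 2 is labelled as reference RNA with the strain of the array's own sample, so levels were not tested between the strains. The reference cancels in the comparison of treated with untreated cells of a strain, and in the difference between the strains' responses. Extraction and labelling followed an earlier publication, per the labels' protocols. The scanner, the filter on weak spots and the normalization are not given in the sources used here.

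The values used are the authors' deposited table of 1 log2 ratio per array and element, with 4109 elements. That the scale is log2 was worked out from the values. On 9 arrays, at least 99.945% of the values raised as powers of 2 were whole multiples of 1 step per array, within 0.05 of a step, against at most 12.2% in base e and 12.4% in base 10. Such steps follow if each array's ratios were recorded in steps of 0.001 and divided by 1 factor, between 0.196 and 2.662 per array. This leaves no correction that varied with intensity within an array after the ratios were recorded. A correction made before that would not show. The 3 arrays of untreated YabA+ cells hold values rounded to 2 decimals, so no step could be recovered there, and log2 was taken from their like range. What the steps say of correction does not cover these arrays. They are the whole group, so any different processing of them could not be told apart from the change in YabA+ cells or the difference between the strains. On 7 arrays a single very high value was repeated, 44 values in 43 elements in all, and on 6 of these arrays it corresponds to a ratio of 100000. These values were taken as placeholders for an unmeasured reference signal, a reading that no source states. They were kept as deposited in the reported results, where 9 tested elements held at least 1, and were left out in an alternative.

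The direction of the ratio is not given in the sources used here and is taken to be sample over reference, which is likely but not settled. It rests on the dyes, which ran the same way on all arrays. Where values were missing did not settle it. Of the elements called higher after HPUra, 16.7% of values were missing on the untreated arrays of YabA+ cells and 0.521% on the treated ones, and 25.4% and 0.57% in yabA-null cells. Of those called lower, 1.36% were missing on either side in YabA+ cells, and 8.33% on the untreated and 1.01% on the treated arrays in yabA-null cells, which is not the side of the weaker sample signal under this direction. With the opposite direction, higher and lower would change places throughout, and the counts, sizes and tests would stay.

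Array medians ran from 0 to 0.146, and 3 lay beyond 0.1, so each array's median was subtracted. An element was tested if it had at least 2 values in each of the 4 groups. That left 2251 elements, while 1858 were not tested, of which 675 had no value on any array. Group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3, with 1 spread per element shared by the 4 groups and moderated across elements. Contrasts were treated minus untreated in each strain and the difference between these responses. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. No pair of arrays held identical values. Few labels speak of cultures, and none says that replicates were grown separately, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of each value. Signal over background is not known, since only ratios were used.

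The element IDs are not paired with genes in any table used here, and 0 of them matched the reference gene table. Gene lists, a trend along the chromosome, the averaging of elements of 1 gene and the level of yabA in the strain that lacks it were therefore not analysed. Elements were named by a fixed rule, as 2 with higher and 2 with lower levels that had the largest fold in YabA+ cells among those past the adjusted threshold, with every treated array beyond every untreated one. The groups, tests, naming rule and first set of alternatives were chosen before the data were examined. Those alternatives were no centring, quantile and scale normalization, other limits on missing values, other moderation, array weights, a replicate block within strain, each strain alone, stricter thresholds and leaving out each array. Alternatives chosen after seeing the data were leaving out placeholders, centring on elements measured on all arrays, centring within classes of detection, leaving out both arrays with the fewest values, keeping the tested elements fixed when an array was left out, and replicate blocks across the strains, some of these in combination. Random blocks used statmod 1.5.0.

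The procedure was tested on simulated data with 200 changed elements among 2251, in 5 simulations per fold, with noise independent between arrays. It recovered 26.1% of 2-fold, 88.8% of 4-fold and 97% of 8-fold changes in YabA+ cells, and 20.8%, 88.1% and 96.8% in yabA-null cells. For the difference between the responses it recovered 0% of 2-fold, 71.9% of 4-fold and 91.7% of 8-fold differences. Replicate numbers in the labels were checked as pairs. Deviations from the group means correlated across the strains between HPUra arrays of the same number at 0.595, 0.472 and 0.574. Untreated arrays of the same number correlated across the strains at -0.444, -0.54 and 0.397. Treated and untreated arrays of the same number within a strain correlated between -0.158 and 0.25, so neither set lay all above 0.1. The reported fits have no block.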

Results

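The transcriptional response to replication arrest was followed in 2 strains of Bacillus subtilis that lack oriC, the chromosomal origin of replication. MMB170 carries yabA and is called YabA+ here. AIG185 lacks it and is called yabA-null. YabA is a negative regulator of replication initiation that binds the initiator DnaA and the sliding clamp DnaN. RNA was taken from untreated cells and from cells given 38 µg/ml HPUra for 60 min. HPUra inhibits PolC, the replicative DNA polymerase, and so stops elongation. The question the series poses is how loss of yabA affects expression after replication arrest.

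Each of the 4 groups had 3 arrays, and each array gave log2 ratios of sample RNA to reference RNA for up to 4109 elements. The IDs of the elements are not paired with genes in the sources used here, so elements are named by ID. In untreated YabA+ cells, replicates 1, 2 and 3 had values for 3225, 2027 and 2367 elements. With HPUra the YabA+ arrays had 2587, 2975 and 3019. In yabA-null cells, the untreated arrays had 1264, 2856 and 2442 and the HPUra arrays 2629, 2954 and 3124. All 12 arrays had a value for 1154 elements, and over these, arrays of the same group correlated with a median r of 0.788 (range 0.577 to 0.911). Arrays of the same treatment but of the other strain correlated as highly, with a median of 0.79 (0.627 to 0.91). Arrays of the same strain but of the other treatment reached a median of 0.297 (0.094 to 0.496). These correlations are across elements, which are not independent replicates. Arrays thus differed more by treatment than by strain, with ratios taken against reference RNA labelled with each strain's own name. The ratio is taken as sample over reference, which is likely but not stated in the sources used here.

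**Figure D1:**
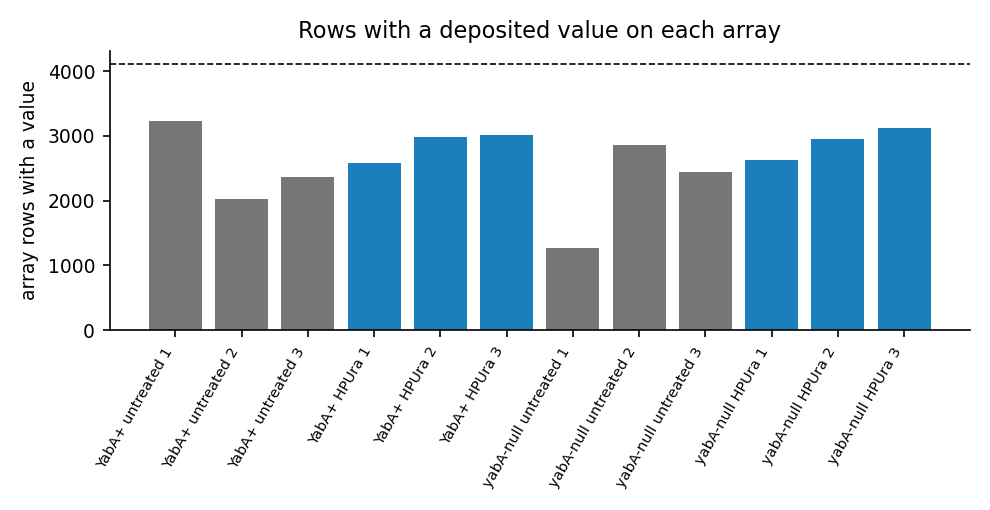
Number of array elements with a deposited value on each of the 12 arrays, shown as bars, with untreated arrays in grey and HPUra arrays in blue. The dashed line marks the 4109 elements of the table, and the lowest bars are yabA-null untreated replicate 1 with 1264 and YabA+ untreated replicate 2 with 2027.

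In YabA+ cells, arrest by HPUra for 60 min was followed by higher levels of 128 elements and lower levels of 123 among the 2251 tested, by limma at an adjusted p under 0.05. Among the called elements increases were larger than decreases, with a median log2 change of 2.86 among the higher elements and -1.35 among the lower. Missing values were uneven, since 16.7% of untreated values were empty for the higher elements and 1.36% for the lower. Whether this affects the sizes was not tested. Of the higher elements, 90 rose at least 4-fold and 32 at least 16-fold, while 22 fell at least 4-fold and 0 at least 16-fold. The largest increase was that of BSO8-2872, from a log2 ratio of -2.95 ± 0.21 (SD, n = 2) in untreated cells to 3.48 ± 0.36 (SD, n = 3) with HPUra. This is a log2 change of 6.42 (SE 0.34), or 85.6-fold, with a limma adjusted p of 4.95e-06. After quantile normalization this log2 change was 9.17. BSO8-2444 rose 47.6-fold, by 5.57 on the log2 scale (SE 0.66, limma adjusted p = 0.000371), from -3.81 ± 0.58 (SD, n = 2) to 1.76 ± 0.17 (SD, n = 3).

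The largest decrease in YabA+ cells was that of BSO8-3956, which fell by 3.56 on the log2 scale (SE 0.24), or 11.8-fold, with a limma adjusted p of 4.95e-06. Its log2 ratio was 1.32 ± 0.32 (SD, n = 3) in untreated cells and -2.23 ± 0.24 (SD, n = 3) with HPUra. BSO8-4032 fell by 3.42 (SE 0.21), or 10.7-fold, from 1.04 ± 0.30 (SD, n = 3) to -2.38 ± 0.15 (SD, n = 3), with the same limma adjusted p of 4.95e-06. After quantile normalization the log2 changes of BSO8-3956 and BSO8-4032 were -4.92 and -4.57. Among changed elements with every HPUra array beyond every untreated array, which were all 128 of the higher and 121 of the 123 lower ones, the 12 largest increases lay between 27.1-fold and 85.6-fold and the 12 largest decreases between 5.03-fold and 11.8-fold. Such separation, seen in 249 of the 251 changed elements, was found in 33.6% of all tested elements and in 13.0% by chance, given each element's number of values. It is likely in elements called from the same values, so it adds no support to the calls. Of the changed elements, 135 lacked a value on at least 1 of the 12 arrays. With the test limited to elements measured on all arrays, the count was 124, of which 27 were higher and 97 lower. Removing 1 array, which takes elements out of the test, gave 160 and 141 without YabA+ untreated replicates 1 and 3. It gave 132 and 137 without yabA-null untreated replicates 2 and 3. The split by direction also moved the other way, to 94 higher and 55 lower at an adjusted p under 0.01. Without YabA+ HPUra replicate 2 it was 104 higher and 68 lower.

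**Figure D2:**
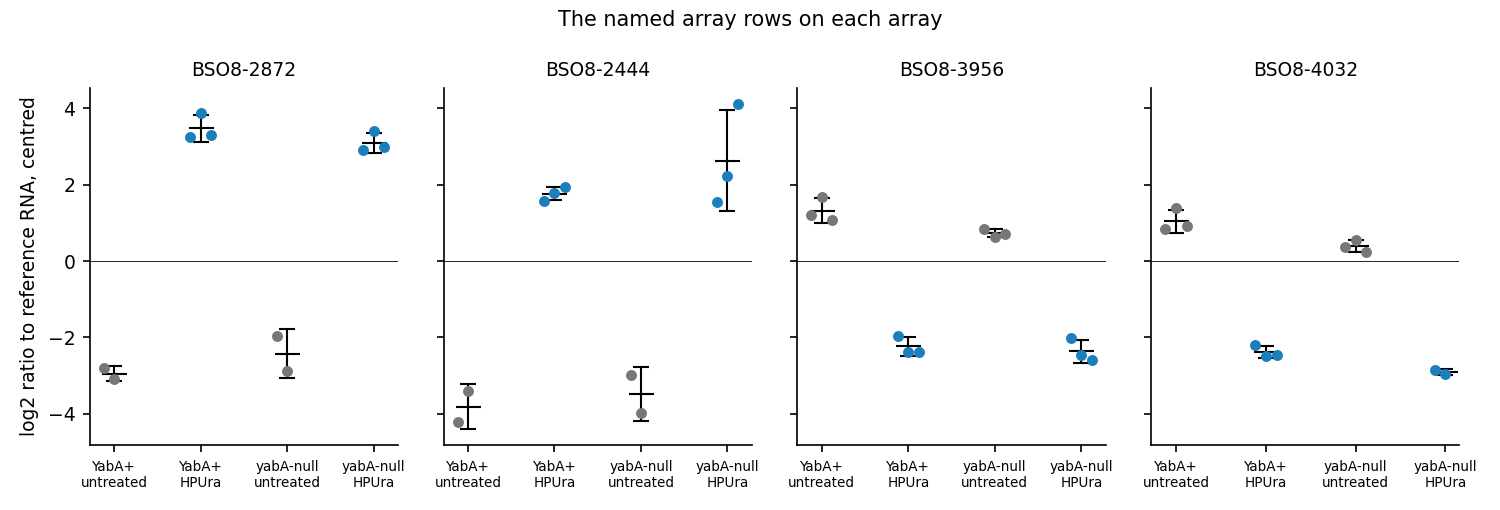
Log2 ratio of sample to reference RNA, centred on each array's median, for the 4 named elements on each array, with untreated arrays in grey and HPUra arrays in blue. Points are single arrays, and bars give the mean and SD of a group. In YabA+ cells BSO8-2872 went from a mean of -2.95 to 3.48, and BSO8-3956 from 1.32 to -2.23.

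In yabA-null cells, the same treatment was followed by higher levels of 117 elements and lower levels of 132 among the same 2251, again by limma. The median log2 change was 3.61 among the higher elements and -1.47 among the lower. At least 4-fold changes were seen in 93 higher and 33 lower elements, and at least 16-fold changes in 46 and 1. BSO8-2872 rose 45.8-fold, by 5.52 on the log2 scale (SE 0.34, limma adjusted p = 4.87e-06), from -2.42 ± 0.64 (SD, n = 2) to 3.10 ± 0.26 (SD, n = 3). BSO8-2444 rose 69.2-fold, by 6.11 on the log2 scale (SE 0.66, limma adjusted p = 0.000162), from -3.49 ± 0.70 (SD, n = 2) to 2.63 ± 1.32 (SD, n = 3). Its log2 change was 4.98 after quantile normalization, and 5.37 to 6.65 when 1 array was left out. BSO8-3956 fell by 3.09 (SE 0.24), or 8.51-fold, from 0.73 ± 0.11 (SD, n = 3) to -2.36 ± 0.30 (SD, n = 3), with a limma adjusted p of 4.87e-06. BSO8-4032 fell by 3.30 (SE 0.24), or 9.83-fold, from 0.39 ± 0.16 (SD, n = 3) to -2.91 ± 0.08 (SD, n = 2), with a limma adjusted p of 5.83e-06.

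The 12 largest increases in yabA-null cells ranged from 34.1-fold to 124-fold, and the 12 largest decreases from 6.97-fold to 16.4-fold. All 249 changed elements had every HPUra array beyond every untreated array, against 34.7% of all tested elements and 15.1% by chance. The calls rest on the same values, which makes such separation likely, so it adds no support of its own. Limited to elements measured on all 12 arrays, the test gave 142 changed elements, 30 higher and 112 lower. The count was 437 with array weights, 161 and 153 without YabA+ untreated replicates 1 and 3, and 145 and 161 without yabA-null untreated replicates 2 and 3, where fewer elements were tested. With the tested elements kept, removal of yabA-null untreated replicate 2 raised it to 387, of which 120 were higher and 267 lower.

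The responses of the strains were set side by side over the 2251 elements. Of the elements called in either strain, 308 in all, 107 were higher in both and 85 lower in both, and 0 were called in opposite directions. Lists of these lengths drawn independently would share 6.65 higher and 7.21 lower elements. The comparisons share no control arrays. They do share 1 spread per element, and HPUra arrays of the same replicate number deviated alike in both strains. The lists are thus not independent, and these expected numbers are only a rough reference. A call was made in YabA+ cells alone for 59 elements and in yabA-null cells alone for 57, which is not a test of a difference. The sign was the same in both strains for 307 of the 308 elements (99.7%). Of changes in YabA+ cells with every HPUra array beyond every untreated array, all 12 of the largest increases were also called in yabA-null cells, as were 8 of the 12 largest decreases. Elements higher in YabA+ cells had a median log2 change of 2.86 there and 3.46 in yabA-null cells, and elements lower in YabA+ cells had -1.35 and -1.27. Across all tested elements, which are not independent replicates, the log2 changes of the strains correlated with a Pearson r of 0.789 and a Spearman rho of 0.64, with a covariance of 0.955. Without the 9 elements holding a placeholder value the Pearson r was 0.846.

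**Figure D3:**
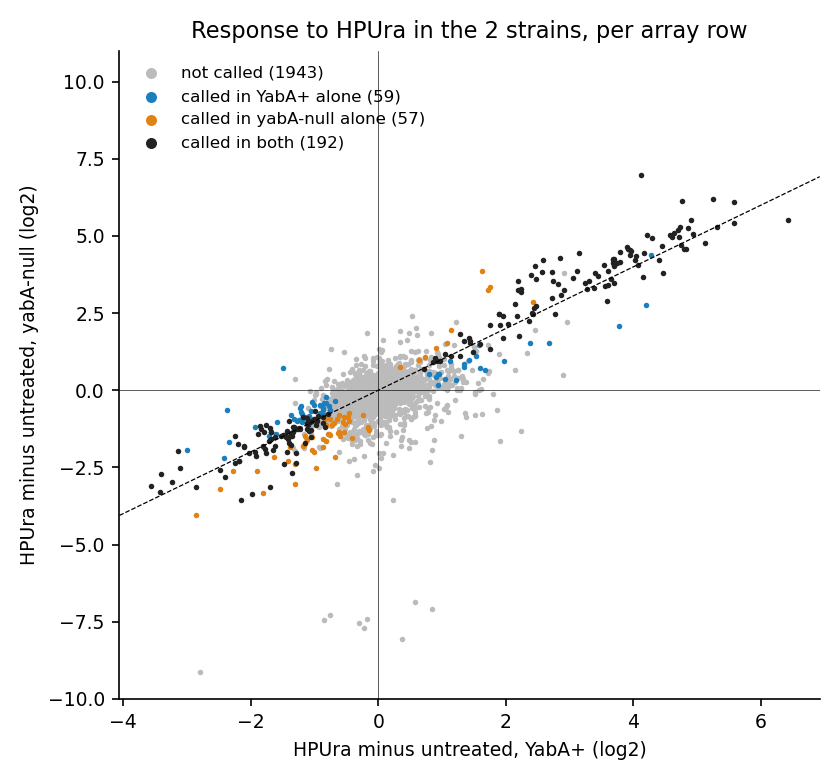
Log2 change after HPUra in YabA+ cells (horizontal axis) against that in yabA-null cells (vertical axis), with 1 point per tested element and the dashed line marking equal changes. Of the coloured points, 192 were called in both strains, 59 in YabA+ alone and 57 in yabA-null alone. Of these 308, 307 have the same sign in both strains.

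Whether loss of yabA changed the response was tested directly, as the difference between the log2 changes of the strains. At an adjusted p under 0.05, limma called 0 of the 2251 elements different. The smallest p was 0.000291, with an adjusted p of 0.656, for an element that changed by -1.49 in YabA+ cells and 0.74 in yabA-null cells. At an unadjusted p under 0.05 there were 48 elements (2.13%), fewer than the 112.55 that chance would give. HPUra arrays of the same replicate number deviated alike in both strains, which this fit leaves out. With treatment by number as a block across the strains, 134 elements (5.96%) had an unadjusted p under 0.05, or 132 without placeholders. That block also pairs the untreated arrays, whose deviations correlated by number at -0.444, -0.54 and 0.397. A random block across the strains, with an estimated correlation of 0.126, gave 69. Among the elements called in either strain the median difference, yabA-null minus YabA+, was 0.06 on the log2 scale. For BSO8-2872 it was -0.90 (95% interval -1.97 to 0.17), and for BSO8-2444 it was 0.54 (-1.56 to 2.64). BSO8-3956 differed by 0.47 (-0.26 to 1.20) and BSO8-4032 by 0.13 (-0.58 to 0.83). All 4 intervals include no difference.

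The intervals set how small a difference these arrays could show. Of the 308 elements called in either strain, the 95% interval of the difference lay within 4-fold either way for 242 (78.6%) and within 2-fold for 63 (20.5%). In simulated data with 200 differing elements among 2251, the test recovered 0% of 2-fold and 71.9% of 4-fold differences. The adjusted threshold depends on how many elements differ, and recovery with fewer than 200 was not simulated. The simulated noise was independent between arrays, unlike that of HPUra arrays of the same replicate number, so these shares are a rough guide. The lack of calls thus does not exclude a 2-fold effect of yabA on elements with wider intervals. At the adjusted threshold, the block of treatment by number gave 4 elements in place of 0, of which 3 held a placeholder value, and 0 with placeholders left out. Leaving out yabA-null untreated replicate 2 gave 0 differing elements among the 1252 that kept at least 2 values per group. With all 2251 elements kept, the others had 1 untreated yabA-null value. The median difference over all elements was then -0.13, against -0.07 as reported. Calls also rose above 0, from a fit that rests partly on single arrays.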

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

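Both counts in this part come from elements outside the tests, and they were chosen as a measure after the pattern of missing values had been seen. Among the elements not tested in YabA+ cells, 27 had a value on all 3 HPUra arrays and on no untreated array, while 0 had the reverse. In yabA-null cells 35 elements did so and 0 had the reverse, with 1 element in both sets. The zeros were limited in advance by sparse untreated arrays and are no even contrast. The reverse needs an element measured on at most 9 arrays, and YabA+ untreated replicate 2 held 133 of these and yabA-null untreated replicate 1 held 1, against 466, 800 and 828 on the HPUra arrays of YabA+ cells. They were singled out because values appeared after HPUra alone, in data that no comparison used. No level or fold can be set against the untreated arrays, which have no value there, and whether the sample signal, the reference signal or the filter on spots left them empty was not tested. With 3 arrays per group, no test for a sample far from the others was run, and no element passed the test of a difference between the strains.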

How the results depend on the processing

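Tests with placeholders left out, other centring, blocks across the strains, both sparse arrays left out or the tested elements kept fixed were chosen only after the results were seen. Over 310 checks (named element by strain by setting), 0 changes reversed and 309 kept their call. The exception was BSO8-2872 in yabA-null cells after quantile normalization (log2 change 4.48, limma adjusted p = 0.152, against 1.08e-06 to 0.0012 otherwise). Many settings could not move the value, and the elements were picked for large changes. Counts for YabA+ cells moved from 251 to 124 with elements on all 12 arrays (1154 tested) and 149 at an adjusted p under 0.01. Those for yabA-null cells moved from 249 to 142 and 157, and to 437 with array weights. All 116 and 118 reported calls on elements with every array were called again in that smaller test. Leaving out 1 array gave 132 to 275 and 145 to 298, partly because fewer elements qualified (down to 1252). The count in YabA+ cells was 160 and 141 without YabA+ untreated replicates 1 and 3, and 132 and 137 without yabA-null untreated replicates 2 and 3. The same 4 removals gave 161, 153, 145 and 161 in yabA-null cells. Lower elements alone went from 123 to 68 in YabA+ cells without YabA+ HPUra replicate 2. In yabA-null cells they went from 132 to 71 without yabA-null HPUra replicate 2. With the tested elements kept, a lone array is assumed to vary like the other groups. There, only removal of yabA-null untreated replicate 2 moved a total of changed elements by over 1.5 times, to 387 in yabA-null cells (378 without placeholders). It also raised the elements differing between strains from 0 to 60 (50 without placeholders), and the cause was not tested. The difference stayed at 0 in 40 of 43 settings, the third exception being the block across strains, with 4. The stricter thresholds among these settings could only give 0, as the reported fit already called 0. The correlation of 0.789 became 0.856 with quantile normalization, 0.868 on elements with every array, 0.652 with 1 value per group, 0.851 with array weights, 0.846 without placeholders and 0.841 without both sparse arrays. It was 0.727 to 0.822 without 1 array. With the elements kept it was 0.74 without YabA+ untreated replicate 1, 0.629 (0.747 without placeholders) without yabA-null untreated replicate 2, and 0.842 without yabA-null untreated replicate 3. The cause of these shifts was not tested. Replicate numbers did not pair treated with untreated arrays within a strain (correlations of deviations from -0.158 to 0.25). As a block within strain they gave 175, 189 and 0 calls. A random block across strains gave 254, 248 and 0. Centring on elements with every array moved the median log2 change of all elements from -0.05 to 0.09 in YabA+ and from -0.15 to -0.01 in yabA-null cells, with 239 and 281 calls. Leaving out both sparse arrays gave 225 and 282. Averaging elements of 1 gene was not run, for lack of gene names. Signal over background is not known, so its limits could not be given.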

Other observations

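The tests of neighbouring IDs, of missing values, of response size with HPUra arrays kept in pairs, of the spread of ratios and of handling by replicate number were chosen only after the result was seen, while those of a sample swap, of few measurable spots, of a hidden difference, of other splits and of response size without pairs were set beforehand.

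Of the 107 elements higher in both strains, 22.4% had a value on all 12 arrays, against 72.9% of the 85 lower in both and 51.3% of all tested elements. Within each array, Spearman's rho across elements between the log2 ratio and the number of other arrays with a value for the element ran from -0.666 to 0.128, and it was below 0 on 10 of the 12 arrays. The median of elements seen on at most 9 arrays exceeded that of elements seen on all arrays on 11 of the 12, by up to 2.21 on the log2 scale. On yabA-null untreated replicate 1, which is among the 11, that median rests on 1 element.

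The mean response over elements called in both strains was set against relabelling of the strains within each treatment. These elements were picked by their calls under the real labels and were not picked again for each relabelling. Elements called in YabA+ cells alone (59) or in yabA-null cells alone (57) were left out, so the comparison does not cover them. A level difference between the strains or their reference RNAs would enter the relabelled responses and widen their spread. Each array entered with the mean over the elements it had, so the arrays compare partly different elements. Of the 107 higher in both, yabA-null untreated replicate 1 had 27 and YabA+ untreated replicate 2 had 52. Of the 85 lower in both, yabA-null untreated replicate 1 had 66. Over the 107 elements higher in both, the mean log2 change was 3.23 in YabA+ and 3.51 in yabA-null cells, an excess of 0.28 in yabA-null cells (exact two-sided permutation p = 0.285, smallest possible 0.005). Leaving out 1 array moved this excess between 0.14 and 0.44. For the 85 lower in both, the means were -1.63 and -1.67, an excess of 0.04 (exact two-sided permutation p = 0.77), which ran from -0.04 without YabA+ untreated replicate 1 to 0.17. On the HPUra arrays alone, yabA-null cells lay beyond YabA+ cells at all 3 replicate numbers, by 0.03, 0.26 and 0.34 over the higher elements and by 0.04, 0.06 and 0.15 over the lower, though these levels also carry any difference between the reference RNAs. Keeping these pairs in 160 relabellings gave exact two-sided permutation p = 0.2 and 0.788 for the response, with 0.0125 the smallest possible. The excess was not beyond 95% of the relabellings, the bound set beforehand against a larger response without yabA. That bound was too weak to exclude one, because a p above the threshold does not show equality, and over the higher elements the excess stayed above 0 without any 1 array. A larger response was not shown.

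Elements with neighbouring ID numbers responded alike. Among the elements higher in YabA+ cells 53 pairs had adjacent numbers, against a mean of 4.84 when the IDs were shuffled (permutation p = 1e-04, the smallest that 10000 shuffles can give), and the longest run was 10. Artefacts of single slides are argued against, since the change in a strain correlated at 0.598 with that of the next ID in the other strain, on other slides. This value is the mean over both orders of the strains. In 1000 shuffles, the change in YabA+ cells correlated with that of the next ID in yabA-null cells at most at 0.0712. An artefact of position shared by all slides would pass this check and was not tested. Clustering of rarely detected elements is argued against by a correlation of 0.709 among elements on all arrays (561 pairs). Coordinate change of neighbouring genes, as in operons or prophages, is a hypothesis left open by the 0.665 between neighbours in YabA+ cells, because nothing used here says that the IDs follow gene order. The likeness reached far, with correlations in YabA+ cells of 0.374 at 10 numbers apart, 0.318 at 20 and 0.0901 at 50.

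YabA+ untreated replicate 2 and yabA-null untreated replicate 1, the arrays with the fewest values, deviated from their groups in the same way (r = 0.573 across 1154 elements), with an SD of deviations of 0.379 and 0.657 against 0.144 to 0.413 on the other 10 arrays. A wider spread of their ratios is argued against, because r was 0.583 after regression on the group means. A swap with treated samples is argued against, because their lowest correlation with other untreated arrays was 0.577 and their highest with HPUra arrays 0.408. Few measurable spots on these arrays could not be told apart from other causes. Over the 6 untreated arrays the leading deviation went with the number of values (Spearman rho 0.771, exact permutation p = 0.103; Pearson r 0.84, exact permutation p = 0.0375; r 0.793 without the 2 arrays farthest from the median), with no adjustment over both.

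HPUra arrays of the same replicate number deviated alike from their group means in both strains, with a mean r of 0.547, and all 6 matched their own number best, while 2 of 6 untreated arrays did, but as changes from the untreated mean yabA-null replicate 2 correlated at 0.824 with its own number and at 0.83 and 0.837 with YabA+ replicates 1 and 3. A spread of ratios shared by number is argued against, because the lowest of the 3 correlations was 0.395 after regression on the group means. Joint handling of cultures or arrays may account for the 0.547, but pairing 3 arrays with 3 gives no exact permutation p under 0.167 and the labels give no batch. Whether the shared numbers hide a difference between the strains stays open, since the block across strains called 4 elements, 3 with a placeholder, and 0 without placeholders. No biological explanation of this pattern was tested.

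Other splits of the arrays were counted for each result. In YabA+ cells 1 of 10 splits, the real one, gave as many as 251 elements, and the highest other gave 2. In yabA-null cells 1 of 10 gave as many as 249, and the highest other gave 9. With 10 splits the share cannot fall under 0.05. For the difference between the strains, a count of 0 is reached by any split, so that the result for all 100 splits drawn was fixed in advance and says nothing about chance. The highest other gave 16. At an unadjusted p under 0.05 the real split gave 48 elements and the median of the others was 79, with up to 360, and 72 of the 100 splits gave as many as 48. The real split puts 1 HPUra array of each replicate number in each strain, and the drawn splits were not held to this. They thus differ from it in kind. With the number as a block across the strains the real split gave 134. Splits with several times the real count point to a structure of the samples. The median was 155 in the 37 splits that put YabA+ untreated replicate 2 and yabA-null untreated replicate 1 under 1 strain, and 54, with up to 220, in the 63 that kept them apart, as the real split does, so these arrays do not account for all of the high counts.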
